A study of Mus musculus with 8 samples.

How the data were processed

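Expression was measured in 8 samples of small-intestinal enterocyte RNA, 4 from WT littermates and 4 from IE-Cpr-null mice. Per the series design, RNA came from 8 male mice of each genotype and RNA of 2 mice was pooled for each array. Per the labels' protocols, enterocytes were isolated from the dissected small intestine, total RNA was extracted with TRIzol and purified on columns, and biotin-labelled antisense RNA was hybridised to single-colour arrays. Sample groups and replicate numbers came from the sample titles. The labels give no batch, scan or litter, so none was tested.

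The deposited table held log2 values per probe set and array. Per the submitters' processing notes the authors used GCRMA, whose version and settings are not given in the sources used here. The values showed that each probe set had also been centred: the median of the 4 WT arrays was 0 within 0.00001 in all 18443 probe sets. Values ran from -10.99 to 12.99, and array medians from -0.0254 to 0.0357. Centring removes the level of expression, so signal over background is unknown, no probe set was left out as dim, and no intensity trend was fitted. The interquartile range over probe sets was 0.06 to 0.10 on the WT arrays, which set the centre, and 0.12 to 0.20 on the IE-Cpr-null arrays. A constant taken from each probe set does not alter its difference between the groups.

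Probe sets were named from the array's platform annotation, with 16689 probe sets carrying 1 gene symbol (10401 genes), 616 several and 1138 not named in it. Probe sets with several symbols or not named were tested but are not named in the text. Symbols were looked up in a mouse gene table of assembly GRCm38.p6 and none (0) needed an update. The files name no genome build and no coordinates are given. The targeted gene is not analysed here, so the genotype labels have no check by its transcript.

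Each probe set was tested with limma (lmFit and eBayes with a constant prior, two-sided) on the values as deposited, with Benjamini-Hochberg adjustment over the 18443 probe sets and a threshold of 0.05. The fit had the 2 group means and no block. The prior had 1.54 degrees of freedom. Genes in lists were tested on the mean of all their probe sets, over 10401 genes, because centred values have no brightest probe set. This replaced the choice written before the data were examined, which was 1 probe set per gene. The filter on dim probe sets planned for levels was dropped for the same reason, as the written plan allowed.

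Before the data were examined, 38 gene lists were fixed, 3 primary lists, 19 further pathway lists and 16 lists of cell type and region markers, with 655 members, 523 of them measured. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the 38 lists, and again with the correlation estimated and with fry. Camera compares a list with all other genes, and fry asks whether its genes move one way on balance. Counts of members past the threshold are given over all genes and with p adjusted over the list alone. Exact permutation tests used the 70 assignments of the arrays to the genotypes, two-sided, with a smallest p of 0.0286. The hepatocyte list and 6 other lists were written after the values were seen.

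Genes named were fixed by a rule before the data were examined. It took up to 12 risen and 12 fallen genes past the threshold with groups that did not overlap, members of primary lists past the threshold, up to 4 members past the threshold of other lists, the member with the smallest p where a list had none, and members of primary lists that failed where needed. Of the probe sets past the threshold, 4 met it. Members that passed only with p adjusted over the list alone were also named. Mt2, Alb and genes in the closing observations were chosen after their values were seen.

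Alternatives tried were quantile normalization, median centring, array weights, replicate number as a block, leaving out probe sets with probes shared between genes (2694 probe sets), a minimum of 1.5-fold, and each array left out in turn. Quantile normalization acted on values already centred on the WT arrays. It gave the narrower WT arrays and the wider IE-Cpr-null arrays the same distribution, which can itself alter differences and spread. Chosen after seeing the data were a robust prior, only probe sets with an SD above the median, counts of genes in place of probe sets, each probe set as a list member, and leaving out the arrays rich in muscle (WT 2 and IE-Cpr-null 1) or hepatocyte transcripts (IE-Cpr-null 2 and 3). The robust prior does not enter the list tests. Its list results repeat the reported ones in every count of settings given for a list.

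The scripts were tested on simulated data with 18443 probe sets and 4 against 4 arrays, each probe set with its own residual SD, and 50 probe sets changed at each of 4 fold sizes. At 1.5-fold 31 were recovered, at 2-fold 45, at 4-fold 50 and at 8-fold 47, with 9 false among 182 calls. With the cholesterol list shifted by 0.5 in simulated gene values, camera called it and 1 other list that was not shifted. The simulated noise was independent between probe sets or genes. The real arrays shared muscle, hepatocyte and acinar signals, so these rates need not hold for them. Analyses used R 4.3.3 with limma 3.58.1, and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. P-values of limma, fry and the permutation tests measure the spread between pools of 2 mice. Camera with the preset correlation rests largely on the spread between genes, taken as nearly independent. The estimated correlation was 0.136 for cholesterol synthesis, 0.556 for MHC class II and 0.85 for pancreatic acinar transcripts. Where genes of a list vary together between pools in this way, the preset camera p is too small.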

Results

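Gene expression was measured in enterocytes, the absorptive epithelial cells of the small intestine, isolated from male C57BL/6 mice aged 2.5 to 3.0 months. IE-Cpr-null mice lack NADPH-cytochrome P450 reductase (Cpr) in the intestinal epithelium. This enzyme passes electrons to microsomal P450 enzymes, including those of sterol synthesis and of drug metabolism. They were compared with wild-type (WT) littermates. Each genotype had 4 arrays and each array carried RNA pooled from 2 mice, so that 8 mice stood behind each genotype and errors measured the spread between pools. The number of arrays limited the precision. The table held 18443 probe sets as log2 values relative to the median of the 4 WT arrays. No expression level was therefore known, and all values below are differences on the log2 scale, IE-Cpr-null minus WT, with n = 4 pools per genotype.

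The first comparison asked which transcripts differed between the genotypes. Mt1, which encodes the metal-binding protein metallothionein 1, rose by 7.29 in its leading probe set (SE 0.077, 156-fold, limma adjusted p = 1.34e-08). The 4 WT arrays lay between -0.033 and 0.027 and the 4 IE-Cpr-null arrays between 7.09 and 7.42. Mt1 sequence carried by the Cre transgene is a candidate explanation left open in the closing observations. The signal may therefore not be a rise of the gene's own transcript. With quantile normalization this Mt1 difference was 4.94 (adjusted p = 0.0403, the highest of a range down to 1.08e-09). Acta1, which encodes skeletal muscle actin, rose by 2.04 (SE 0.145, 4.11-fold, adjusted p = 0.00953). Sqle, which encodes the squalene epoxidase of cholesterol synthesis, rose by 1.34 (SE 0.12, 2.53-fold, adjusted p = 0.0268). Slc23a2, which encodes a sodium-dependent vitamin C transporter, fell by 0.89 in its leading probe set (SE 0.066, adjusted p = 0.00953).

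These 4 probe sets, 3 higher and 1 lower, were all that passed an adjusted p of 0.05 in limma among the 18443 tested. At an unadjusted p under 0.05, 539 probe sets were higher and 825 lower, 1364 in all, where chance gives 922.15. Every IE-Cpr-null array lay above every WT array in 303 probe sets and below in 455, together 4.11% of probe sets, where chance gives 2.86%. A second Mt1 probe set was 3.00 higher (SE 0.319) but missed the threshold (adjusted p = 0.0677), so the size of the Mt1 change depended on the probe set. Mt2, the neighbouring metallothionein, was chosen after its values were seen. Its difference of 0.79 (SE 0.705, adjusted p = 0.86) lay within the spread, with WT arrays between -1.11 and 1.55 and IE-Cpr-null arrays between -0.37 and 1.54. A second Slc23a2 probe set differed by -1.20 (SE 0.235) and missed the threshold (adjusted p = 0.252). Transcripts of stromal and muscle cells were high on 1 IE-Cpr-null array, replicate 1, where the mean of that marker list was 3.53 against -0.32 to -0.34 on the other IE-Cpr-null arrays. Acta1 was 1.74 on that array and 1.91 to 2.45 on the others. Quantile normalization between arrays left 1 probe set higher and 0 lower in limma (261 and 382 at an unadjusted p under 0.05), and median centring 2 higher and 1 lower. A call lost with quantile normalization cannot be told from an effect of that step on centred values. Leaving out WT replicate 1, 2 or 4 also left 1 higher and 0 lower, leaving out IE-Cpr-null replicate 1 gave 12 higher and 4 lower, leaving out IE-Cpr-null replicate 2 gave 6 higher, and array weights gave 352 higher and 389 lower. Of these calls Sqle held in 8 of 18 settings (difference 1.24 to 1.45, adjusted p from 0.00265 to 0.97). It was lost with quantile normalization (1.36), median centring (1.33) and the replicate block, without the muscle-rich (1.24) or hepatocyte-rich arrays (1.45), without WT replicate 1 (1.34), 2 (1.29) or 4 (1.29), and without IE-Cpr-null replicate 3 (1.36) or 4 (1.32). Acta1 held in 12 of 18 (1.86 to 2.14, adjusted p from 0.000313 to 0.97) and Slc23a2 in 11 (-0.94 to -0.70, adjusted p from 0.00265 to 0.295), both lost without WT replicate 1, 2 or 4, without the muscle-rich arrays, with quantile normalization and with the replicate block. Slc23a2 was also lost without the hepatocyte-rich arrays.

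**Figure D1:**
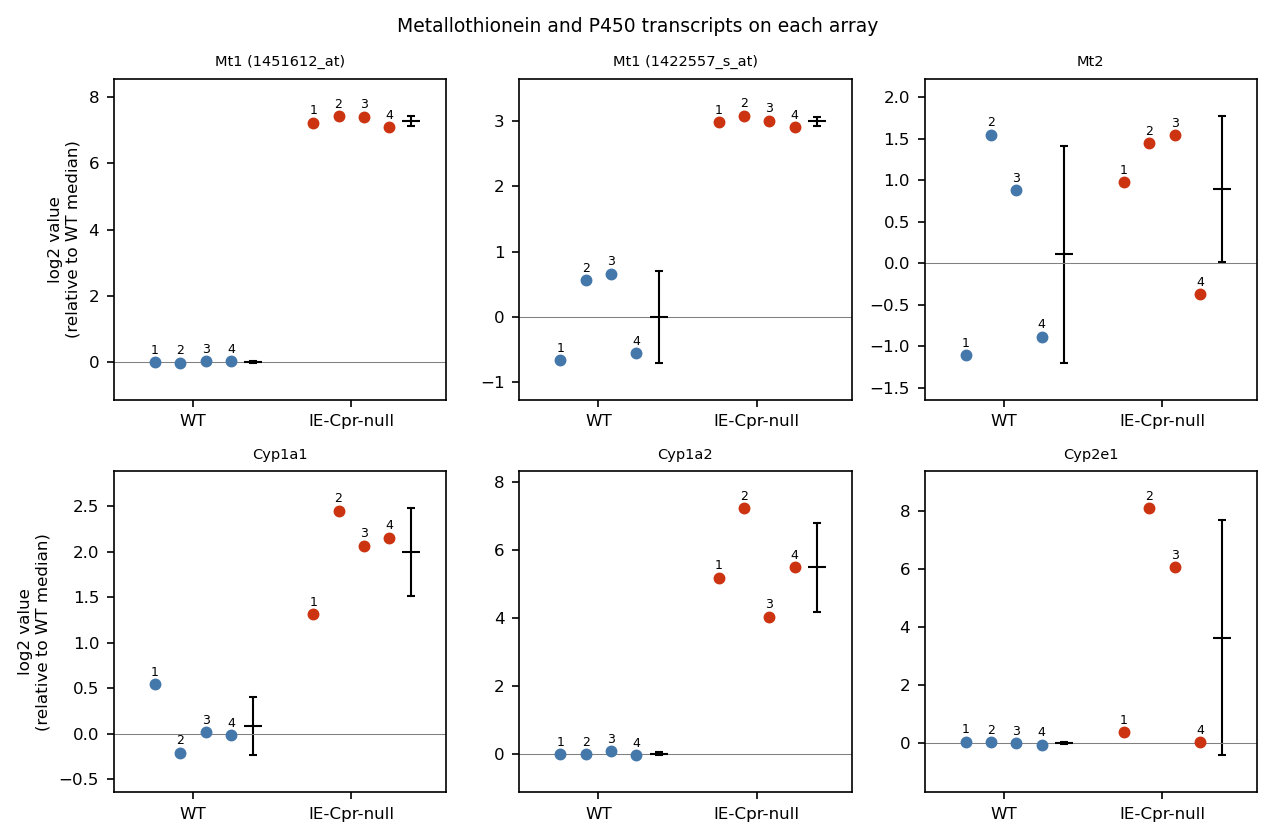
Log2 value relative to the WT median on each array for both Mt1 probe sets, Mt2, Cyp1a1, Cyp1a2 and Cyp2e1. Points are arrays (n = 4 per genotype) with their replicate number, and the bar beside them is the mean with its SD. Both Mt1 probe sets, Cyp1a1 and Cyp1a2 were higher on each IE-Cpr-null array than on any WT array, Mt2 overlapped, and Cyp2e1 reached 8.11 and 6.06 on IE-Cpr-null replicates 2 and 3 alone.

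Genes of cholesterol synthesis were higher in IE-Cpr-null enterocytes. Of the 19 measured members of this list, 17 were higher and 2 lower, with a median difference of 0.42. Besides Sqle, the largest differences were those of Mvd, the mevalonate diphosphate decarboxylase (1.34, SE 0.192), Pmvk, the phosphomevalonate kinase (0.94, SE 0.156), Idi1, the isopentenyl diphosphate isomerase (0.79, SE 0.148), and Cyp51, the lanosterol demethylase and itself a P450 enzyme (0.75, SE 0.102). The list mean ran from 0.36 to 0.62 on the IE-Cpr-null arrays and from -0.03 to 0.11 on the WT arrays. Pancreatic acinar transcripts also differed between the groups, with array means of -1.81 to -4.66 in IE-Cpr-null. In WT they stood at -4.45 on replicate 3, which had the highest WT cholesterol mean, and at -0.62 to 1.44 on the others. The cholesterol mean of that WT array was 0.11, below the lowest IE-Cpr-null mean of 0.36. IE-Cpr-null replicate 1, with the highest acinar mean of its group (-1.81), had the highest cholesterol mean (0.62). Without WT replicate 3 the cholesterol median was 0.43. No WT array low in acinar transcripts was then left, so that setting cannot separate the 2 patterns.

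Over all genes, 1 member of the cholesterol list passed the threshold, Sqle (gene-level adjusted p = 0.0184, and from 0.00136 to 0.933 over 18 settings, of which it passed in 9). With p adjusted over the list alone, 13 members passed, all higher: Sqle, Mvk, Tm7sf2, Fdps, Cyp51, Mvd, Hmgcs1, Pmvk, Fdft1, Idi1, Nsdhl, Hsd17b7 and Lss. The groups did not overlap in 12 of the 19. Members that passed neither way included Srebf2, the transcription factor of the pathway (0.24, SE 0.12), Dhcr7 (0.11, SE 0.0617), Sc5d (0.025, SE 0.0479) and Ebp (-0.049, SE 0.0512). In camera with a preset correlation the list passed (adjusted p = 6.19e-18). It did not pass there with the correlation estimated from the arrays (adjusted p = 0.0694 with an estimated correlation). In fry it passed (adjusted p = 0.00254). An exact permutation test of the list mean gave p = 0.0286, the smallest that 4 against 4 arrays allow (adjusted p = 0.181 over the 38 lists). Without the 2 arrays rich in muscle transcripts 14 members passed with p adjusted over the list alone, and without the 2 rich in hepatocyte transcripts 13.

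**Figure D2:**
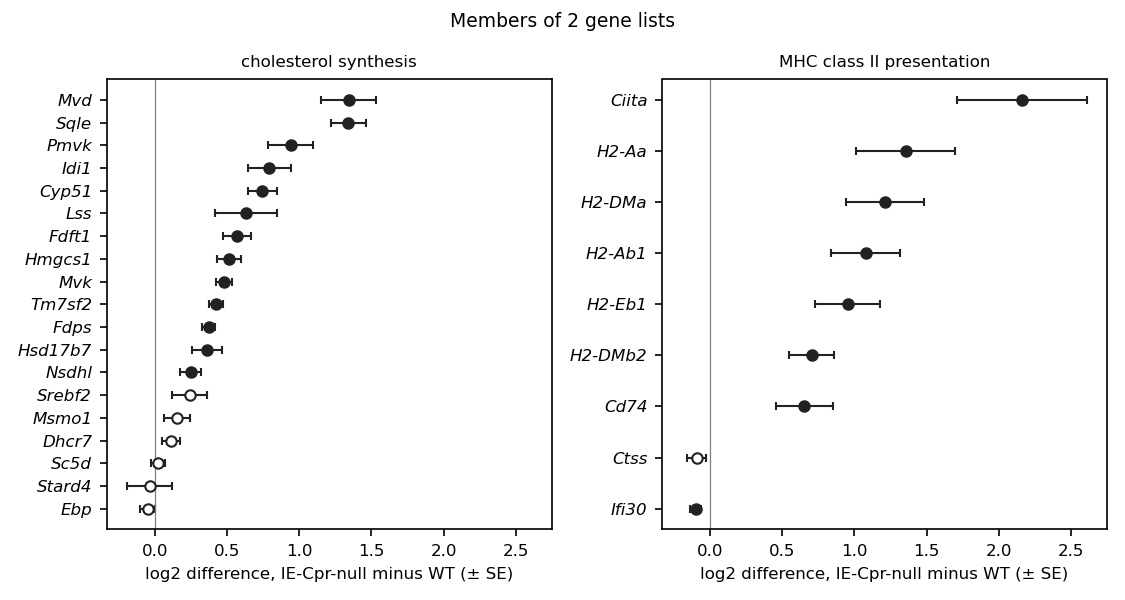
Log2 difference, IE-Cpr-null minus WT, of each measured member of the cholesterol synthesis list (19 genes) and the MHC class II list (9 genes), with its limma SE (n = 4 arrays per genotype). Filled points passed with p adjusted over the list alone: 13 cholesterol genes, all higher, and 8 MHC class II genes, of which Ifi30 was lower, a call lost without any 1 WT array or without IE-Cpr-null replicate 1 or 2.

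MHC class II genes, whose products present peptides to helper T cells, were also higher in IE-Cpr-null enterocytes. Of the 9 measured members, 7 were higher and 2 lower, with a median difference of 0.95. Ciita, the class II transactivator, was 2.16 higher (SE 0.449), H2-Aa 1.36 higher (SE 0.343), H2-DMa 1.21 higher (SE 0.268), H2-Ab1 1.08 higher (SE 0.24) and the invariant chain gene Cd74 0.65 higher (SE 0.197). The WT arrays were themselves uneven, with list means of -0.43, -0.27, 0.41 and 0.26, all below the IE-Cpr-null means of 0.66, 0.89, 1.06 and 0.89. The highest of these WT means was that of replicate 3, the WT array low in acinar transcripts (-4.45), and without it the list median was 1.12. That setting leaves no WT array low in acinar transcripts, so it cannot separate the list from the acinar difference.

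No MHC class II gene passed over all genes in limma (0 of 9; the smallest unadjusted p was 0.00163, for Ciita, adjusted p = 0.222). With p adjusted over the list alone, 7 passed as higher (Ciita, H2-Aa, H2-DMa, H2-Ab1, H2-Eb1, H2-DMb2 and Cd74) and 1 as lower, Ifi30, a lysosomal thiol reductase (-0.099, SE 0.0402). Without any 1 WT array, without IE-Cpr-null replicate 1 or 2, and without the muscle-rich or hepatocyte-rich arrays, 0 members passed as lower. The study is known to have reported on these genes, so this list is not independent evidence of their direction. The list passed in camera (adjusted p = 3.38e-05) but not with the correlation estimated (adjusted p = 0.323 with an estimated correlation), and not in fry (adjusted p = 0.155). An exact permutation test of the list mean gave p = 0.0286 (adjusted p = 0.181). The macrophage and dendritic cell list, whose cells also carry MHC class II, had a mean difference of -0.33, and the B cell and plasma cell list one of 0.09, with 9 of 10 members higher. Without IE-Cpr-null replicates 2 and 3, which were rich in hepatocyte transcripts, 2 IE-Cpr-null arrays were left and 0 members passed in limma with p adjusted over the list alone. The list median was then 0.896 and the list passed in camera (adjusted p = 0.0096, and from 1.64e-10 to 0.323 over all settings). Without the muscle-rich arrays 6 members passed, with a list median of 0.93.

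**Figure D3:**
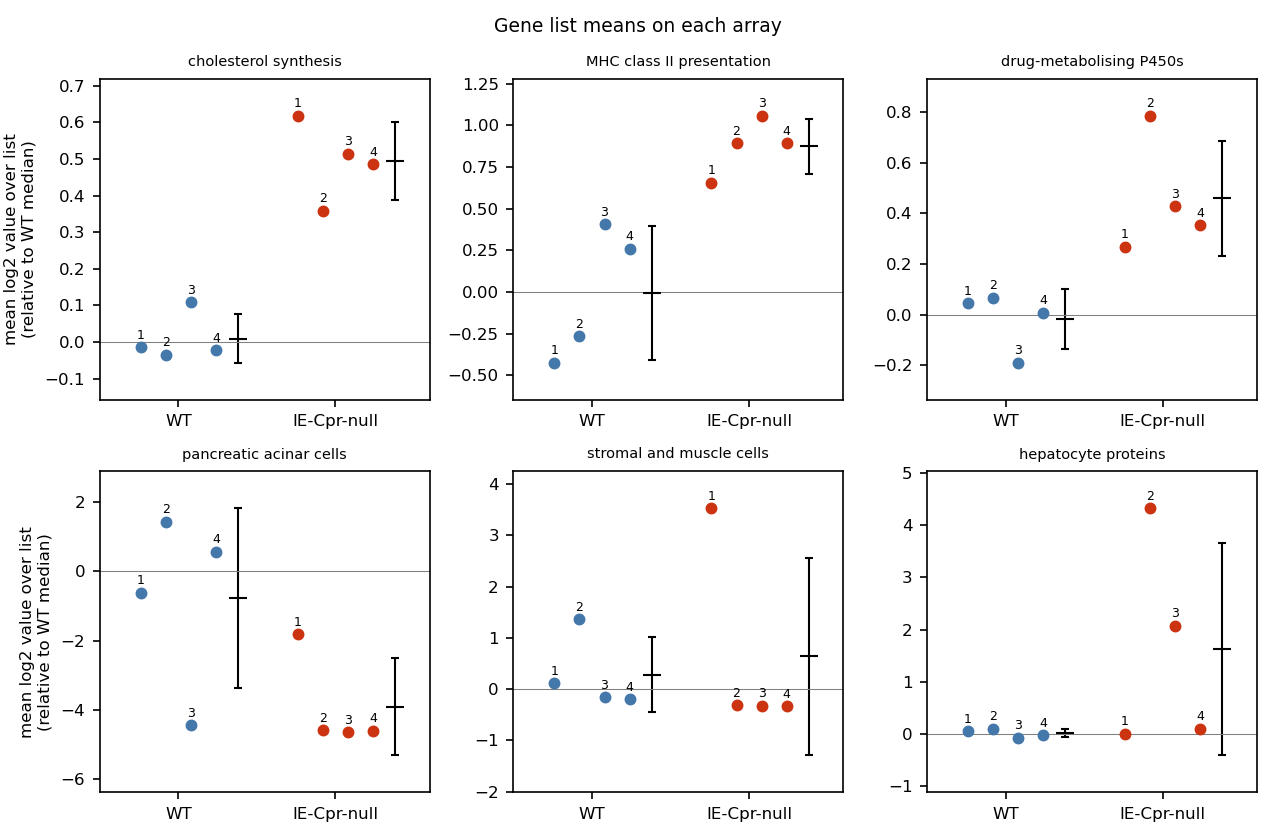
Mean log2 value over each gene list on each array, relative to the WT median, for the 3 primary lists (top) and for pancreatic acinar, stromal and muscle, and hepatocyte transcripts (bottom). Points are arrays (n = 4 per genotype) with their replicate number, and the bar beside them is the mean with its SD. The cholesterol synthesis, MHC class II and P450 means were higher on each IE-Cpr-null array than on any WT array. The medians over the P450 list overlapped, at -0.010 to 0.047 in IE-Cpr-null and -0.057 to 0.043 in WT. Acinar means were -4.45 or lower on WT replicate 3 and IE-Cpr-null replicates 2 to 4, and -1.81 on IE-Cpr-null replicate 1. Stromal and muscle means were highest on IE-Cpr-null replicate 1 (3.53) and WT replicate 2 (1.36). Hepatocyte means were highest on IE-Cpr-null replicates 2 (4.33) and 3 (2.08).

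Among drug-metabolising P450s, 2 members of the Cyp1a family stood out and most others differed little. Cyp1a2 was 5.47 higher (SE 0.589, 44.5-fold) and Cyp1a1 1.91 higher (SE 0.259, 3.77-fold), each higher on all 4 IE-Cpr-null arrays than on any WT array. Cyp2d26 was lower, with a difference of -0.39 (SE 0.0487). The median over the 28 measured members was 0.04, with 19 higher and 9 lower, and the mean 0.48. Over all settings this median ran from 0.013, without WT replicate 3, to 0.20, with only probe sets of SD above the median, and it was 0.062 without WT replicate 2. Cyp3a11 (0.04, SE 0.0759) and Cyp3a13 (0.0065, SE 0.0462), of the main drug-metabolising subfamily, lay within their spread.

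No member of the P450 list passed over all genes in limma, where 904 genes had an unadjusted p under 0.05. Cyp1a2 had an adjusted p of 0.0537, Cyp2d26 of 0.0677 and Cyp1a1 of 0.0793. Cyp1a2 passed in 6 of 18 settings (adjusted p from 4.28e-05 to 0.418), among them without the hepatocyte-rich arrays, where its difference was 5.32, and without IE-Cpr-null replicate 1 (5.57), 2 (4.89) or 3 (5.96). With quantile normalization its difference was 3.80, with the highest p of that range. Cyp1a1 passed in 3 of 18 (adjusted p from 0.00151 to 0.933), among them without IE-Cpr-null replicate 1 (2.14), and Cyp2d26 in 2 of 18. With p adjusted over the list alone, these 3 genes passed, 2 higher and 1 lower. The list did not pass in camera (adjusted p = 0.187). Hepatocyte transcripts, a list written after the values were seen, were high on IE-Cpr-null replicates 2 and 3, with means of 4.33 and 2.08, and lay between -0.07 and 0.10 on the other 6 arrays. Alb, the albumin gene of hepatocytes, was 9.32 and 7.91 on those arrays, 1.40 on IE-Cpr-null replicate 4 and 1.70 on WT replicate 2. Cyp2e1, an abundant liver P450, was 8.11 and 6.06 there and 0.37 and 0.02 on the remaining IE-Cpr-null arrays. Cyp2d9 was 4.08 on IE-Cpr-null replicate 2 and at most 0.06 on the other IE-Cpr-null arrays. Cyp1a2 was 7.23 and 4.04 on replicates 2 and 3, and 5.19 and 5.49 on replicates 1 and 4.

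Of the 19 other pathway lists, 5 passed in camera at an adjusted p of 0.05. Genes of fatty acid oxidation and of the PPARa response fell as a list (20 measured, 15 lower, median -0.08, adjusted p = 0.000327, adjusted p = 0.314 with an estimated correlation). No member passed over all genes in limma, and with p adjusted over the list alone 4 did, all lower: Pdk4, the pyruvate dehydrogenase kinase (-1.65, SE 0.436), Acaa2 (-0.51, SE 0.15), the carnitine palmitoyltransferase Cpt1a (-0.28, SE 0.0801) and Acadvl (-0.12, SE 0.0327). The median of this list was -0.043 with quantile normalization, where it still passed. Immediate early and heat shock genes rose as a list (21 measured, 20 higher, median 0.16, adjusted p = 0.000939, adjusted p = 0.232 with an estimated correlation), and with p adjusted over the list alone 1 member passed, Jun (0.28, SE 0.058). Their array means overlapped, at 0.18, 0.12, -0.02 and -0.08 in WT and 0.71, 0.36, 0.09 and 0.25 in IE-Cpr-null, highest on the muscle-rich replicate 1 (exact permutation p = 0.0857, adjusted p = 0.271). The median of that list was 0.092 with quantile normalization and 0.10 without the hepatocyte-rich arrays, where it still passed.

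The other 3 calls were less even across settings. The aryl hydrocarbon receptor targets rose as a list (adjusted p = 0.0331, adjusted p = 0.323 with an estimated correlation), with a mean of 1.01 but a median of 0.04 over 7 genes. Its 2 members past the threshold with p adjusted over the list alone were Cyp1a1 and Cyp1a2. It passed in 17 of 21 settings (adjusted p from 0.00786 to 0.323), not without WT replicate 3 (median 0.026) or with the replicate block (adjusted p = 0.0971). Its median was 0.017 with only probe sets of SD above the median, 0.14 without the muscle-rich arrays, 0.068 without the hepatocyte-rich arrays, 0.063 without WT replicate 1, 0.024 without WT replicate 4 and 0.11 without IE-Cpr-null replicate 1. The interferon response list rose (27 measured, 19 higher, median 0.13, adjusted p = 0.0429, adjusted p = 0.623 with an estimated correlation), with Gbp2, a guanylate-binding protein gene, at 1.12 (SE 0.245) and no member past either threshold. Its mean was -0.12 on IE-Cpr-null replicate 1 and highest, at 0.43, on replicate 2. This list passed in 13 of 21 settings (adjusted p from 7.16e-05 to 0.734). It did not pass without the hepatocyte-rich arrays (median 0.041), without WT replicate 2 (0.13), or without IE-Cpr-null replicate 2 (0.048) or 3 (0.12), nor with the replicate block or without probe sets that share probes. Where it passed, its median was 0.078 without WT replicate 3, 0.084 without WT replicate 4, 0.26 without IE-Cpr-null replicate 1 and 0.26 without the muscle-rich arrays. Retinoid metabolism fell as a list (14 measured, 12 lower, median -0.09, adjusted p = 0.0429, adjusted p = 0.318 with an estimated correlation), with the retinol dehydrogenase gene Rdh7 at -0.43 (SE 0.145) and no member past either threshold. It passed in 13 of 21 settings (adjusted p from 0.0117 to 0.318). It did not pass without the muscle-rich arrays (median -0.041), without WT replicate 2 (-0.065) or 4 (-0.055), without IE-Cpr-null replicate 1 (-0.019) or 3 (-0.089), or with only probe sets of SD above the median (-0.145), and its median was -0.13 without WT replicate 3. Its array means overlapped, at -0.11, -0.03, -0.07 and 0.16 in WT and -0.15, -0.06, -0.24 and -0.08 in IE-Cpr-null (exact permutation p = 0.171, adjusted p = 0.407).

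The other 14 pathway lists did not pass in camera in the reported setting. Over 21 settings, phase II conjugation passed in 5 (lowest camera adjusted p = 0.00014) and MHC class I presentation in 4 (0.000187). In 3 of them 1 member passed with p adjusted over the list alone: Scd2, a stearoyl-CoA desaturase gene of fatty acid synthesis (1.65, SE 0.374, list median 0.07), Sdf2l1 of the unfolded protein response (0.39, SE 0.0492, list median 0.06), and Pcna of the cell cycle list (-0.26, SE 0.0471, list median -0.03). The fatty acid synthesis list had a mean of 0.72 on IE-Cpr-null replicate 1 and 0.03 to 0.09 on the other IE-Cpr-null arrays. List medians were 0.12 for MHC class I presentation and 0.03 for antimicrobial and epithelial defence, whose mean (-0.02) had the opposite sign. They were -0.03 for phase II conjugation, -0.06 for NRF2 targets, -0.05 for haem synthesis and degradation, -0.02 for alternative electron donors and partners, and -0.05 for eicosanoid metabolism. They were -0.06 for LXR targets and sterol export, -0.05 for bile acid handling, -0.02 for chylomicron assembly and fat absorption, and -0.08 for the circadian clock. Array means of the circadian clock list did not overlap, at -0.27 to -0.07 in IE-Cpr-null and -0.06 to 0.11 in WT. The exact permutation test gave p = 0.0286 (adjusted p = 0.181), and the list passed in camera in 2 of 21 settings.

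The cell type and region markers asked which cells the preparations held. Absorptive enterocyte markers differed little between the genotypes (12 measured, median -0.03, camera adjusted p = 0.229), and 1 of them, the glucose transporter gene Slc2a2, passed as lower with p adjusted over the list alone (-0.28, SE 0.0604). Pancreatic acinar transcripts, which encode digestive enzymes, fell as a list (10 measured, all lower, median -3.64, adjusted p = 3.13e-06, adjusted p = 0.323 with an estimated correlation). Their array means were -0.62, 1.44, -4.45 and 0.58 in WT and -1.81, -4.60, -4.66 and -4.61 in IE-Cpr-null, so that WT replicate 3 lay with the IE-Cpr-null arrays. Goblet cell markers fell as a list (11 measured, 10 lower, median -0.17, adjusted p = 0.00221, adjusted p = 0.232 with an estimated correlation), with Fcgbp at -0.18 (SE 0.0486) and no member past either threshold. Their mean was 0.38 on IE-Cpr-null replicate 1 and -0.27 to -0.48 on the other IE-Cpr-null arrays. The goblet list passed in 17 of 21 settings (adjusted p from 9.74e-06 to 0.232), not without the hepatocyte-rich arrays (median -0.14) or with only probe sets of SD above the median. Its median was -0.37 without IE-Cpr-null replicate 1, -0.36 without the muscle-rich arrays and -0.11 without IE-Cpr-null replicate 2. Enteroendocrine markers fell as a list (14 measured, 10 lower, median -0.24, adjusted p = 0.00221, adjusted p = 0.323 with an estimated correlation). With p adjusted over the list alone, 4 were lower (Chga, Chgb, Neurod1 and Tph1, at -0.24 to -0.50) and neurotensin, Nts, was higher (0.56, SE 0.174). Macrophage and dendritic cell markers fell as a list (18 measured, 13 lower, median -0.09, adjusted p = 0.0429, adjusted p = 0.318 with an estimated correlation), with no member past either threshold. They passed in 11 of 21 settings (adjusted p from 0.00528 to 0.318). They did not pass with median centring or array weights, without the muscle-rich arrays (median -0.076) or the hepatocyte-rich arrays (-0.08), without WT replicate 2 (-0.052) or 3 (-0.06), or without IE-Cpr-null replicate 2 (-0.097) or 3 (-0.058). Where they passed, the median was -0.14 without WT replicate 4 and -0.15 without IE-Cpr-null replicate 4, and -0.25 with only probe sets of SD above the median. Array means overlapped between the genotypes for the goblet, enteroendocrine and macrophage lists (exact permutation p = 0.343, 0.0571 and 0.0857, adjusted p = 0.521, 0.217 and 0.271).

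The other 11 marker lists did not pass in camera in the reported setting, and none of their members passed either threshold in limma. Over 21 settings, T cells and intraepithelial lymphocytes passed in 6 (lowest camera adjusted p = 0.000704). Duodenum and proximal small intestine passed in 4 (0.00378). List medians were -0.26 for duodenum and proximal small intestine and 0.04 for ileum and distal small intestine, whose mean was -0.16. They were 0.06 for stem and crypt base cells, whose mean was -0.09, and -0.30 for Paneth cells. These last 2 lists stood at 0.72 and 1.29 on IE-Cpr-null replicate 1 and below 0 on the other IE-Cpr-null arrays. List medians were -0.12 for tuft cells, 0.11 for T cells and intraepithelial lymphocytes, 0.11 for B cells and plasma cells, 0.03 for granulocytes and mast cells, 0.04 for endothelial cells and 0.05 for red blood cells. The stromal and muscle list, whose mean was 3.53 on IE-Cpr-null replicate 1 and 1.36 on WT replicate 2, had a median of 0.29 with all arrays. It passed in 2 of 21 settings, in opposite directions: as lower without IE-Cpr-null replicate 1 (median -0.28, adjusted p = 0.0212) and as higher without the hepatocyte-rich arrays (0.896, adjusted p = 0.00651, the lowest of a range up to 0.804). Without both muscle-rich arrays the median was -0.045 (adjusted p = 0.0916). In all, 11 of the 38 lists passed in camera, 0 with the correlation estimated and 1 in fry.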

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

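With 4 arrays in a group, a value was singled out where its gap to the nearest of the others, over the group's range, exceeded Dixon's critical value, which chance exceeds in about 5% of groups. This held in 8 of 76 groups of list means, where chance gives 3.8, and 7 of 84 groups of gene values, where chance gives 4.2. Sqle counts in the 84 both as a probe set and as a gene. All values are log2 relative to the WT median.

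IE-Cpr-null replicate 1 stood apart in 3 list means. Its stromal and muscle mean was 3.53 against -0.34 to -0.32 on the other IE-Cpr-null arrays, its pancreatic acinar mean -1.81 against -4.66 to -4.60, and its fatty acid synthesis mean 0.72 against 0.03 to 0.09. The endothelial mean of IE-Cpr-null replicate 2 was 0.18 against 0.05 to 0.06 on the others of its group.

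Among the WT arrays, replicate 3 had a cholesterol synthesis mean of 0.11 against -0.03 to -0.01 on the others, still below the lowest IE-Cpr-null mean of 0.36, and an enteroendocrine mean of -0.18 against 0.0029 to 0.02. Replicate 1 had a chylomicron assembly and fat absorption mean of -0.0523 against 0.01 on the others, and an interferon mean of 0.0886 against -0.04 to -0.03.

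Single genes stood apart in the same way. Acaa2 was -0.50 and Tph1 -0.52 on WT replicate 3, each with the others between -0.01 and 0.06. Pmvk was -0.30 on WT replicate 2 against -0.00406 to 0.03. Acta1 was -0.15 on WT replicate 4 against -0.0069 to 0.01 on the other WT arrays, and Tm7sf2 was -0.0358 there against -0.00094 to 0.0046. H2-DMb2 was 1.03 on IE-Cpr-null replicate 3 against 0.53 to 0.59, and Slc2a2 was -0.15 on IE-Cpr-null replicate 4 against -0.35 to -0.32.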

How the results depend on the processing

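Planned before the data were examined were all alternatives except leaving out the muscle-rich or hepatocyte-rich arrays, the SD filter, the robust prior, gene-level counts and each probe set as a list member. Probe set counts of 3 higher and 1 lower became 1 and 0 with quantile normalization, 352 and 389 with array weights (weights of 6.49 for IE-Cpr-null 4, 2.84 for WT 4 and 0.33 to 0.99 for the others), and 6 and 1 with the SD filter, which tests fewer probe sets. They became 1 and 2 without the muscle-rich arrays, while the count of lower became 0 without the hepatocyte-rich arrays and 0 for genes, where the probe sets of a gene are averaged. With 1 array left out, higher ran from 1 to 12 and lower from 0 to 4, with the highest counts without IE-Cpr-null 1. Mt1 passed in all 18 settings that refit the probe sets, the reported one included, Acta1 in 12, Slc23a2 in 11 and Sqle in 8. Array weights shared all 4 calls.

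Of 38 lists 11 passed, 0 with an estimated correlation, 1 in fry, 20 with each probe set as a member, and 8 to 17 with 1 array left out (17 without IE-Cpr-null 1). The cholesterol median of 0.424 lost its call with an estimated correlation and passed in 20 of 21 settings, between 0.379 and 0.499. The 21 settings include the reported one and the robust prior, which repeats it for lists and adds no check. The MHC class II median of 0.953 lost its call with an estimated correlation and in fry, and passed in 19 of 21. The P450 median was 0.0583 without the muscle-rich arrays (adjusted p = 0.0418) and 0.0511 with each probe set as a member (adjusted p = 0.0486), the only settings in which it passed (adjusted p from 0.0418 to 0.623). The stromal and muscle median turned to -0.283 without IE-Cpr-null 1 (-0.283 to 0.472 with 1 array left out), with WT 2, which also carried those transcripts, kept. Without both it was -0.045 (adjusted p = 0.0916, from 0.00651 to 0.804 over all settings). Where fewer probe sets, genes or arrays do not account for a change, the cause was not tested. Among the other 35 lists, 582 comparisons with an alternative gave the same call and sign of the median, 42 lost and 36 gained a call, and 1 gained a call with the opposite sign. In another 37, over 17 lists, the sign changed with no call on either side, with medians of -0.251 to 0.113. Of the 582, 35 came from the robust prior, where no list result could change. Among 42 results of named genes, in which Sqle counts both as a probe set and as a gene, 634 comparisons were the same, 32 lost and 45 gained a call.

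Replicate numbers are shared between genotypes, and the labels do not say whether they pair the arrays. Deviations of same-numbered arrays correlated at -0.06, -0.04, 0.26 and 0.13. Those of WT 2 and IE-Cpr-null 1, both rich in muscle transcripts, correlated at 0.34, so these values do not decide it. With the replicate block, 1 probe set was higher and 0 lower, and 12 lists passed. Not run were a stricter filter on dim probe sets, a floor of 16, an intensity trend and the brightest probe set per gene, which need levels that centred values lack. No filter is the reported setting. Signal over background is unknown.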

Other observations

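The mitochondrial, glucocorticoid, immunoglobulin, metal and hepatocyte lists and the tests on Mt1, the Cyp1a genes and MHC class II were chosen after the values were seen. The tests against other splits of the arrays were set before.

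On lists written after the values were seen, transcripts of mitochondrial energy metabolism were slightly lower in IE-Cpr-null enterocytes. The p-values below come from those same values and are not an independent test. Of 84 measured genes of the respiratory chain, 75 were lower, with a median of -0.056 and array means of -0.09 to -0.05 in IE-Cpr-null against -0.01 to 0.01 in WT. None of the 84 passed either threshold in limma, and 14 were lower and 0 higher at an unadjusted p under 0.05. Of 19 genes of the tricarboxylic acid cycle and pyruvate oxidation, 17 were lower (median -0.076). With p adjusted over that list alone 5 passed in limma, all lower: Dlat, Fh1, Idh3a, Idh3b and Idh3g, at -0.41 to -0.12. Of 74 mitochondrial ribosome genes, 59 were lower (median -0.068), with Mrpl44 lower (-0.29) and Mrps15 higher (0.22) past the threshold with p adjusted over the list alone. Camera gave adjusted p values of 3.62e-12, 9.76e-08 and 4.11e-08 for these lists. They were adjusted p = 0.0572, 0.0225 and 0.0821 with an estimated correlation. The second list gave adjusted p = 0.16 with an estimated correlation without the muscle-rich arrays, 0.115 without the hepatocyte-rich arrays and 0.129 without IE-Cpr-null replicate 1. Its medians there were -0.072, -0.096 and -0.071 with fewer arrays, and its adjusted p with the preset correlation 3.72e-05, 3.62e-05 and 7.79e-06. All 3 medians stayed below 0 with quantile normalization and with median centring. Exact permutation tests of the array means gave p = 0.0286 for each, the smallest possible (adjusted p = 0.0667 over the 7 lists).

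Genes induced by glucocorticoids were also lower as a list (12 measured, 8 lower, median -0.30, camera adjusted p = 0.0229, adjusted p = 0.335 with an estimated correlation). With p adjusted over the list alone 3 passed in limma, all lower: Pdk4, Sgk1 (-0.89) and Sesn1 (-0.27). The array means overlapped, at 0.02, -0.45, 0.11 and 0.14 in WT and 0.02, -0.53, -0.85 and -0.45 in IE-Cpr-null. The list did not pass with quantile normalization (median -0.22, adjusted p = 0.395), without the hepatocyte-rich arrays (-0.11, adjusted p = 0.738), without WT replicate 3 (-0.29, 0.123) or 4 (-0.27, 0.0742), or without IE-Cpr-null replicate 3 (-0.24, 0.272), in a range from 3.4e-05 to 0.738. Immunoglobulin genes had a median of -0.08 over 21 genes (adjusted p = 0.154, and 0.0391 to 0.703 with other settings), passing as lower only without WT replicate 1 (-0.13). Their median was 0.0095 without WT replicate 3, -0.041 without WT replicate 2, -0.048 without WT replicate 4 and -0.051 without the hepatocyte-rich arrays. Besides Mt1, 4 genes that answer metals or oxidants had a median of 0.13 (adjusted p = 0.258). All 26 hepatocyte genes were higher (median 1.37), a difference carried by IE-Cpr-null replicates 2 and 3.

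Other splits of the 8 arrays into 4 and 4 show how far chance can be excluded, counting 35 splits with the real one. For cholesterol synthesis 1 split, the real one, gave a camera p as small, with a -log10 p of 18.79 against 12.52 in the next. That is the smallest share 35 splits can give. It speaks against chance for that list taken alone but does not exclude it, with no adjustment for the other results tested in this way. In the exact permutation test of list means, the cholesterol, MHC class II and P450 lists all reached the same smallest p of 0.0286 (adjusted p = 0.181). So did the lists of aryl hydrocarbon receptor targets, of PPARa and fatty acid oxidation, and of the circadian clock. Array medians of the P450 list overlapped between the genotypes, so its p does not show a rise of most members. By the camera p, chance is not excluded for MHC class II, where 3 splits gave one as small (5.574 against 5.736 in the highest other). Nor is it for the P450 list, where 14 did (0.9269 against 2.986). It is not excluded for the number of lists, where 7 splits gave as many as the real 11 (up to 13), or for the number of probe sets, where 2 splits gave as many as the real 4 (8 in the other). That other split sets WT replicate 3 and IE-Cpr-null replicates 2 to 4 against the rest, which are the arrays with pancreatic acinar means of -4.45 or lower against -1.81 or higher, and 2 of its 8 probe sets, those of Cela3b and Cela2a, are on the acinar list.

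Mt1 was higher on all 4 IE-Cpr-null arrays. A metallothionein response to metal or stress would raise Mt2 as well, and the lowest IE-Cpr-null value of Mt2 lay below the highest WT value (a gap of -1.923). This speaks against a rise of Mt2 as large as that of the leading Mt1 probe set. The WT values of Mt2 spread widely, so a smaller rise could overlap too, and a response with such a rise is not excluded. RNA from liver or muscle in some pools would leave out replicate 4, where both of those lists lay within 0.5 of 0, yet the mean of the Mt1 probe sets exceeded its highest WT value there by 4.666 and each Mt1 probe set ranged over at most 0.3305 across the 4 arrays. That range goes with a candidate explanation left open, Mt1 sequence carried by the Cre transgene, which would give a nearly constant value. Whether this transgene holds such sequence is not given in the sources used here, and an effect of the genotype on Mt1 alone, without Mt2, stays open and untested.

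Cyp1a1 and Cyp1a2 were higher on all 4 IE-Cpr-null arrays. Hepatocyte RNA in some pools would leave replicates 1 and 4 at the WT level, yet their lower value exceeded the highest WT value by 5.103 for Cyp1a2 and by 0.7742 for Cyp1a1. The second gap passes a bound of the WT SD (0.321) but not the bound of 1 written first, and both bounds were set after the values were seen. An aryl hydrocarbon receptor response would raise the other 5 measured targets too, but their median difference was 0.01715. Aldh3a1 (0.043, SE 0.042), Cyp1b1 (0.041, SE 0.049), Nfe2l2 (0.017, SE 0.11) and Tiparp (0.015, SE 0.143) differed little. Nqo1 was lower (-0.42, SE 0.296). The values show no rise common to these 5 genes. The SE of Nfe2l2, Tiparp and Nqo1 exceeded the bound set for counting this against the receptor, so the test does not decide. Signal over background of the 5 genes is also unknown, and an aryl hydrocarbon receptor response stays open. An effect of the genotype on Cyp1a1 and Cyp1a2 stays open, as untested.

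MHC class II genes were higher on each IE-Cpr-null array, a pattern for which chance is not excluded. More macrophages and dendritic cells in the preparations would raise their markers too, and that list differed by -0.3349 in its mean and -0.088 in its median. Its array means overlapped between the genotypes, and signal over background of these markers is unknown. More B cells would raise theirs, which stays open for replicate 3 (list median 0.41), but on the other 3 IE-Cpr-null arrays the B cell and plasma cell mean was at or below the highest WT array and the median 0.052, 0.03 and 0.016 (at most 0.017 in WT), beside MHC class II means of 0.66 to 0.89, which speaks against B cells as the whole cause. An interferon response could raise Ciita, and it stays open: the interferon list differed by 0.18, with a mean of -0.12 on IE-Cpr-null replicate 1 and 0.18 to 0.43 on the others. Uneven WT arrays stay open as well, since MHC class II and macrophage means were both highest on WT replicate 3 (0.41 and 0.43) and both lowest on WT replicate 1 (-0.43 and -0.25).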
